A study of Mus musculus with 8 samples.

How the data were processed

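The series holds 8 RNA-seq libraries of mouse metaphase II oocytes, 4 labelled Ctrl (genotype WT, L/L) and 4 labelled KO (L/L cre), from females of about 6 months. Per the labels' protocol, merged oocytes were lysed and amplified by Smart-seq2. Samples were grouped by their titles. The replicate numbers come from the same titles.

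The deposited table holds TPM for 469 rows and 8 library columns, each matched to 1 sample by its name. Per the submitters' processing notes, kallisto 0.46.2, sleuth 0.30.1 and genome build GRCm38 were used. The annotation release, the normalization before deposit and the rule by which the 469 rows were chosen are not given in the sources used here. TPM divide each estimated read count by transcript length and scale each library to a fixed total, so a fall of abundant transcripts raises all others slightly. Up to 4 rows share a gene name and no row carries a transcript identifier. The rows are read here as transcripts. As all rows differed at least 2.04-fold between the group means, the table is taken as a preselected list. Multiple-testing adjustment and list tests therefore run among preselected rows only. The library totals and the genes outside the list were not analysed here, and sequencing depth is unknown. No pair of libraries held identical values.

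Rows of one gene name were summed, which gave 417 genes, 4 of them with rows of opposite direction. Genes with a mean of at least 1 TPM over the 8 libraries were kept, which left 402 genes and took out 15. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Zeros can be failed estimates of a transcript, so ranges or single values are given for some of the genes with zeros, and the fold changes of the others rest in part on such values. Sums per library were compared by exact two-sided permutation tests, for which 4 against 4 libraries cannot go below p = 0.0286. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the rest.

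The 27 gene lists, the test, the rule for named genes and the alternatives were set before the data were examined. Lists with at least 3 kept genes, 6 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, and with fry. The named genes are the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean of at least 5 TPM in the higher group and no overlap between the groups, up to 4 members with the smallest p of each list, and Sod2, Tfam, Polg, Twnk, Polrmt, Zp3 and Gdf9. Predicted genes and pseudogenes were not named under the first part of this rule. Other members of the mitochondrially encoded and chaperone lists, with Gm28438, Gm20594 and Srp54a, were named after their values were seen. Gene positions and types come from GENCODE M21 (GRCm38), where 416 of the 417 names matched and 410 were protein coding. The remaining name had been turned into a date and is left unnamed.

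Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, leaving out the mitochondrially encoded genes with rescaling, eBayes without trend or with robust fitting, array weights, the replicate number as a block, a 2-fold minimum, and each library left out in turn. Rows kept unsummed, and Ctrl replicates 2 and 4 left out together, were added after seeing the data. Median-of-ratios scaling and quantile normalization were computed from the listed rows alone. A call lost under them can therefore come from scaling rows that were picked for their difference. Count-based tools were not run, since TPM are not counts and keep no depth.

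The limma step was tested on simulated data for the 402 genes, with 200 genes changed by known amounts in each of 20 draws. It recovered 35.4% of the genes changed by 1 on the log2 scale and 94.2% of those changed by 2, with 2.48% false among its calls. With no gene changed it made 0 calls. The simulated noise was normal and independent between genes, without factors per library, excess zeros or preselected rows. The deposited values differ in these respects, so these rates do not give the error rates of the calls reported here. Near-identical copies of named genes were searched for with megablast among the GENCODE M21 transcripts, at 95% identity over at least 200 bp.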

Results

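Transcripts of mature (metaphase II) mouse oocytes were compared between 4 libraries from females of about 6 months labelled L/L cre (KO) and 4 libraries from L/L females of the same age (Ctrl). The design text asks which transcripts change in oocytes when reactive oxygen species in the mitochondrial matrix are raised. Cre is a recombinase that deletes marked stretches of DNA. The labels do not name the gene that was targeted, so the loss of the target could not be checked here. Each library was made with Smart-seq2, a full-length cDNA method for very small inputs, from merged oocytes. The deposited values are TPM, a transcript's abundance corrected for its length and scaled to a fixed total per library, in 469 rows that carry 417 gene names, and 44 genes have 2 or more rows. Rows of one gene name were summed, so a gene stands here for its listed transcripts and not for its whole output. The listed rows added up to between 32000 and 42538 TPM in the Ctrl libraries and between 12869 and 19916 TPM in the KO libraries. These sums were 3.54% ± 0.484 (SD, n = 4) of the total to which TPM are scaled in Ctrl and 1.69% ± 0.305 (SD, n = 4) in KO. They are not sequencing depth, which TPM do not keep and which is unknown.

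In the deposited TPM, 10 mitochondrially encoded messenger RNAs were lower in KO than in Ctrl oocytes. For each, all 4 KO libraries lay below all 4 Ctrl libraries. Under median-of-ratios scaling 5 passed. Under quantile normalization, which sets values by rank, none passed and mt-Nd2, mt-Atp6 and mt-Cytb were not lower. For mt-Atp6 and mt-Cytb, at ranks 1 and 2 in all 8 libraries, that scaling cannot show a fall. The summed level of the 10 was 25580 ± 2725 TPM (SD, n = 4) in Ctrl and 10364 ± 3889 TPM (SD, n = 4) in KO. This was a 2.47-fold difference (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow). The nuclear transcripts went both ways. Among cytosolic chaperone and heat shock genes, a list that did not pass as a whole (camera adjusted p = 0.394), Cct5, Hspa8 and Dnaja1 were lower. Cct4 and the regulator Hsf1 were higher, both at low levels (group means from 0.716 to 2.53 TPM and from 0.225 to 1.87 TPM). The Cct4 call was lost when some single libraries were left out. Mfhas1 and its chromosomal neighbour Eri1 moved in opposite directions. Of 402 genes tested, 377 passed the limma adjusted p threshold of 0.05, with 147 higher and 230 lower in KO.

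These counts describe rows that already differed between the groups. All 469 rows differed at least 2.04-fold in mean TPM, and in 57.1% of them the 4 KO libraries lay wholly above or below the 4 Ctrl libraries, against 2.86% by chance. The counts, p-values and list tests are therefore not independent evidence of a difference. Genes without a row, among them Sod2, Tfam, Polg, Twnk, Polrmt, Zp3 and Gdf9, were not analysed here. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

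The mitochondrially encoded list had 10 of its 15 genes in the table, and all 10 fell (limma adjusted p from 0.0041 to 0.0177, also 10 adjusted over the list alone). Their log2 fold changes ran from -2.13 for mt-Nd3 to -1.21 for mt-Nd2, with a median of -1.49. The listed genes lie between positions 2751 and 15288 of the mitochondrial chromosome (GRCm38). The mt-Nd genes encode subunits of respiratory complex I, and mt-Cytb, mt-Co3 and mt-Atp6 encode cytochrome b, a cytochrome c oxidase subunit and an ATP synthase subunit. For mt-Nd4 the level was 1368 ± 318 TPM (SD, n = 4) in Ctrl and 428 ± 150 TPM (SD, n = 4) in KO, a log2 fold change of -1.73 ± 0.35 (SE; limma adjusted p = 0.0041). For mt-Nd4l it was 2332 ± 375 TPM (SD, n = 4) against 713 ± 329 TPM (SD, n = 4), a log2 fold change of -1.86 ± 0.41 (SE; limma adjusted p = 0.00503). The 2 most abundant members, mt-Atp6 and mt-Cytb, went from 7417 to 3175 TPM and from 5937 to 2554 TPM in the group means. KO library 2 stood lowest, with 5157 TPM over the 10 genes against 9827 to 14088 TPM in the other KO libraries, and all 10 genes still passed without it. Without Ctrl replicate 4, 9 passed (mt-Atp6 at adjusted p = 0.0502), and without Ctrl replicates 2 and 4 together, left out after seeing the data, 2 passed with all 10 still lower.

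At the preset inter-gene correlation of 0.01, the mitochondrially encoded genes as a group were lower than the other listed genes (limma camera adjusted p = 0.0325). The correlation estimated for this list was 0.84, far above the preset value. With the estimated correlation the call was lost (camera adjusted p = 0.704). It was also lost without Ctrl replicate 1 (adjusted p = 0.0571), Ctrl replicate 3 (0.0796) or KO replicate 3 (0.0565), under median-of-ratios scaling (0.0883) and quantile normalization (0.808), with the replicate block (0.0615) and with a pseudocount of 0.1 (0.065). All 10 genes were lower under median-of-ratios scaling too, where 5 passed. Quantile normalization gives equal values to equal ranks, and mt-Atp6 and mt-Cytb shared ranks 1 and 2 in all 8 libraries, so it cannot show whether such top-ranked genes fell. None of the 10 passed under it, and mt-Nd2, at ranks 7 to 9, had a log2 fold change of 0.0553. By fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, the list passed (adjusted p = 0.00914), as lists of rows picked for their difference can. Several of these genes have a copy in the nuclear genome of nearly the same sequence. For mt-Nd3 the copy Gm28438 is identical over 99.7% of 345 bp, is itself listed and was lower as well, at 1406 ± 325 TPM (SD, n = 4) in Ctrl and 372 ± 233 TPM (SD, n = 4) in KO, a call lost under quantile normalization (adjusted p = 0.0593).

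**Figure D1:**
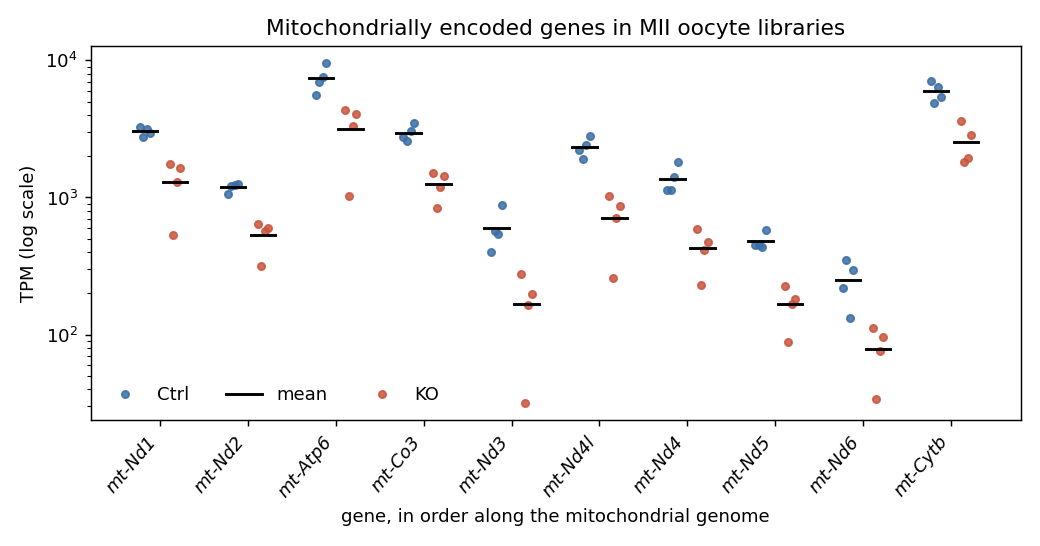
TPM (log scale) of the 10 listed mitochondrially encoded genes in each of the 4 Ctrl (blue) and 4 KO (red) libraries, with black bars at the group means. In the deposited TPM the KO points of each gene lie below all of its Ctrl points. Under quantile normalization, which sets values by rank, none of the 10 passed and mt-Nd2, mt-Atp6 and mt-Cytb were not lower. For mt-Atp6 and mt-Cytb, at ranks 1 and 2 in all 8 libraries, that scaling cannot show a fall.

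The cytosolic chaperone and heat shock list had 8 of its 24 genes in the table. Chaperone genes outside this list were not counted. Of the 8, 6 fell and 2 rose (limma, also 6 and 2 adjusted over the list alone). The list as a whole did not pass against the other listed genes (camera adjusted p = 0.394, and 0.704 with an estimated correlation). It passed by fry (adjusted p = 0.00914, and 0.000766 for changes in either direction). Under median-of-ratios scaling 3 fell and 2 rose, under quantile normalization 4 fell and 2 rose, and without Ctrl replicates 2 and 4 together 1 fell and 1 rose. Their median log2 fold change was -1.83. Cct5, a subunit of the chaperonin that folds actin and tubulin, was at 12.6 to 18.0 TPM in Ctrl and 0 to 1.44 TPM in KO (log2 fold change -3.11 ± 0.47 SE, limma adjusted p = 0.000664). Hspa8, the constitutive Hsp70 chaperone, was at 14.5 to 34.3 TPM against 0 to 7.86 TPM (-2.85 ± 0.59 SE, limma adjusted p = 0.0041). Dnaja1, an Hsp40 partner of Hsp70, fell by 3.18 on the log2 scale (SE 0.86, limma adjusted p = 0.012), although the Ctrl range of 8.40 to 155 TPM overlapped the KO range of 0.0101 to 16.9 TPM. Tcp1, Hsp90ab1 and Cct2 also fell, with calls lost under median-of-ratios scaling, those of Hsp90ab1 and Cct2 also under quantile normalization, and that of Cct2 without Ctrl replicate 2 (adjusted p = 0.0532). The risers were Cct4 and Hsf1. Cct4, another chaperonin subunit, overlapped between the groups. It lost its call without Ctrl replicate 2 or 4 or KO replicate 2 or 3 (limma adjusted p = 0.0626 to 0.0993) and with array weights (0.141). Hsf1, the main transcription factor of the heat shock response, was at 0 to 0.556 TPM in Ctrl and 1.33 to 2.18 TPM in KO (log2 fold change 1.24 ± 0.32 SE, limma adjusted p = 0.00998).

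Among nuclear genes for mitochondrial proteins, few had a row and they did not share a direction. Opa1, which fuses the inner mitochondrial membrane, was at 1.10 to 2.89 TPM in Ctrl and was listed at 0 in all 4 KO libraries (limma adjusted p = 0.00283). Ndufa10 of complex I fell (log2 fold change -2.47 ± 0.70 SE, limma adjusted p = 0.014), although its call was lost under median-of-ratios scaling (adjusted p = 0.066). In complexes II to V, Uqcrq rose from 23.8 ± 7.82 to 70.7 ± 9.71 TPM (SD, n = 4 each; limma adjusted p = 0.00524) and Cox7a2l fell from 47.5 ± 14.7 to 21.1 ± 6.79 TPM (SD, n = 4 each; limma adjusted p = 0.0212). The Cox7a2l call was lost without Ctrl replicate 2 (adjusted p = 0.0568) or KO replicate 2 (0.0525) and under both scalings. Of 3 mitochondrial ribosome genes, Mrpl13 and Dap3 fell and Mrps21 rose (camera adjusted p = 0.80, fry adjusted p = 0.0944), and all 3 calls were unsteady. Leaving out KO replicate 4 ended the call of Mrpl13 (adjusted p = 0.0576), any 1 of Ctrl replicates 2, 3 and 4 and KO replicates 2 and 4 that of Dap3 (0.0507 to 0.0795), and any 1 of Ctrl replicates 1, 3 and 4 and KO replicates 1, 2 and 3 that of Mrps21 (0.0521 to 0.0879). Median-of-ratios scaling also ended those of Mrpl13 (adjusted p = 0.124) and Dap3 (0.281). For maintenance of mitochondrial DNA, the helicase and nuclease Dna2 rose (log2 fold change 1.78 ± 0.46 SE, limma adjusted p = 0.0103) and Rrm2b, a subunit of ribonucleotide reductase, fell (-1.72 ± 0.52 SE, limma adjusted p = 0.0147), a call lost under median-of-ratios scaling (adjusted p = 0.143). The groups overlapped for Dna2, with 1.01 TPM after rounding in both Ctrl library 1 and KO library 1. They also overlapped for Rrm2b, Ndufa10 and Mrps21. All calls in these lists were the same when adjusted over the list alone.

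All 3 genes of the spindle, kinetochore and cohesin list that had a row fell. Cep192, a centrosome scaffold, had a log2 fold change of -2.22 ± 0.56 (SE, limma adjusted p = 0.0091; 3.15 TPM in KO library 3 against 2.66 TPM in Ctrl library 3), Haus6 of the augmin complex -1.88 ± 0.54 (SE, limma adjusted p = 0.014) and Spc25 of the outer kinetochore -1.21 ± 0.39 (SE, limma adjusted p = 0.0178). The list did not pass against the other listed genes (camera adjusted p = 0.337) and passed by fry (adjusted p = 0.00914), and Haus6 and Spc25 lost their calls under median-of-ratios scaling. In the list for translation and decay of maternal messenger RNA, Eif4e1b, an oocyte form of the cap-binding protein, fell by 1.38 on the log2 scale (SE 0.41, limma adjusted p = 0.0144), a call lost under median-of-ratios scaling (adjusted p = 0.138). Pum2 and Cnot6l fell as well. Both calls were lost when Ctrl replicate 2 or 4 was left out, that of Pum2 also without KO replicate 1 or 4 (adjusted p = 0.0528 to 0.0687) and that of Cnot6l without KO replicate 2 or 3 (0.0638 to 0.0935). Both were also lost under median-of-ratios scaling (adjusted p = 0.134 for Pum2 and 0.354 for Cnot6l) and quantile normalization (0.0566 and 0.123). Array weights ended that of Cnot6l too (limma adjusted p = 0.109). Dcp1a, a cofactor of messenger RNA decapping, rose from 2.44 ± 1.22 to 8.70 ± 2.17 TPM (SD, n = 4 each, limma adjusted p = 0.016). That list did not pass as a group (camera adjusted p = 0.80, fry adjusted p = 0.0944). These counts were the same when adjusted over the list alone.

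Among oocyte and maternal effect genes, Nlrp9b fell from 190 ± 33.1 to 91.1 ± 15.9 TPM (SD, n = 4 each; limma adjusted p = 0.0144). Its call was lost under median-of-ratios scaling (log2 fold change -0.25, adjusted p = 0.254) and quantile normalization (-0.30, adjusted p = 0.421). Dnmt1, the maintenance DNA methyltransferase, passed over all genes (log2 fold change -0.91 ± 0.40 SE, limma adjusted p = 0.0414) but not when adjusted over the list alone (0.0556), and its call was lost without Ctrl replicate 2 or 4 or any 1 KO replicate (adjusted p = 0.0593 to 0.147), under median-of-ratios scaling (log2 fold change -0.10, adjusted p = 0.69) and under quantile normalization (-0.08, adjusted p = 0.788). The replicate block (limma adjusted p = 0.0635), eBayes without trend (0.065) and array weights (0.144) ended the Dnmt1 call too. Nlrp4f, whose 3 rows went in opposite directions, had a log2 fold change of -0.44 ± 0.43 (SE, limma adjusted p = 0.323). This list did not pass against the other listed genes (camera adjusted p = 0.647) and passed by fry (adjusted p = 0.0289). For DNA repair, Brca2, at 0 in 3 Ctrl libraries, rose (1.58 ± 0.42 SE, limma adjusted p = 0.0117) and Brca1 fell (-1.40 ± 0.56 SE, limma adjusted p = 0.0314), the latter with its call lost when any 1 of Ctrl replicates 1, 2 and 4 and KO replicates 2 and 4 was left out (adjusted p = 0.0523 to 0.0961), under median-of-ratios scaling (0.207) and under quantile normalization (0.0985). The proteasome subunit Psma6 was at 1.07 to 2.61 TPM in Ctrl and at or near 0 in KO (limma adjusted p = 0.00332). Rps14 of the small ribosomal subunit rose (2.36 ± 0.78 SE, limma adjusted p = 0.0191), a call lost without Ctrl replicate 4 (adjusted p = 0.058). Rpl22, Ern1 and Rpia did not pass, with limma adjusted p of 0.517, 0.0537 and 0.106. The 2 rows of Rpl22 went in opposite directions, from 8.98 to 3.29 TPM and from 0.87 to 8.64 TPM in the group means, and it passed as higher under median-of-ratios scaling (adjusted p = 0.0149). Ern1 passed as lower with a pseudocount of 5 (0.04998), eBayes without trend (0.0367) or with robust fitting (0.0497), and without Ctrl replicate 1 (0.046) or KO replicate 3 (0.0466). Adjusted over the list alone, the calls of the DNA repair, proteasome and ribosomal lists were the same. No gene of the other 12 lists had a row. Genes of the same themes that the lists leave out can still be in the table. These 12 lists were not analysed here. They cover matrix redox enzymes, NRF2 targets, the integrated stress response, apoptosis, meiotic cell cycle regulators, the tricarboxylic acid cycle, fatty acid oxidation, iron-sulfur enzymes, interferon response, genome activation, and markers of cumulus and granulosa cells and of stromal, endothelial, blood and immune cells.

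The largest fall among the named genes was that of Rsl1d1, a nucleolar ribosome biogenesis protein (chromosome 16, 11192970 to 11203331, GRCm38), at 20.1 to 283 TPM in Ctrl and 0 to 1.26 TPM in KO (log2 fold change -5.93 ± 0.68 SE, limma adjusted p = 6.54e-05). Helq, a DNA helicase of crosslink repair, was at 16.5 to 94.0 TPM in Ctrl and 0 to 6.29 TPM in KO (log2 fold change -3.81 ± 0.69 SE). Usp46, a deubiquitinase, was at 31.7 to 226 TPM in Ctrl and 4.56 to 19.5 TPM in KO (log2 fold change -3.17 ± 0.58 SE). Eri1, an RNA 3′ exonuclease, was at 4.43 to 8.66 TPM in Ctrl and at 0 in 3 KO libraries, with 0.613 TPM in KO library 1 (log2 fold change -2.75 ± 0.42 SE, limma adjusted p = 0.000664). The other genes that the naming rule gave among the 12 largest falls were Cct5, Hspa8, Trmt6, Rttn, Hbs1l, Adamtsl1, Med8 and Hnrnpa3. Their log2 fold changes ran from -3.11 to -2.26. The rule left out genes whose groups overlapped, among them Dnaja1 (log2 fold change -3.18). Rttn lost its call under median-of-ratios scaling (adjusted p = 0.0618).

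Mfhas1 was at 7.87 to 14.7 TPM in Ctrl and 86.5 to 92.7 TPM in KO (log2 fold change 2.91 ± 0.34 SE, limma adjusted p = 6.54e-05). It lies on chromosome 8 from 35587798 to 35679449, next to Eri1 at 35465253 to 35496196 (GRCm38). Ube4b, a ubiquitin ligase, was at 0, 0, 4.99e-06 and 1.10 TPM in the Ctrl libraries and at 5.06 to 17.5 TPM in KO (log2 fold change 3.46 ± 0.51 SE, limma adjusted p = 0.000664). Ccdc14 was at 0.000114 to 3.84 TPM in Ctrl and 10.5 to 57.6 TPM in KO (log2 fold change 3.30 ± 0.60 SE, limma adjusted p = 0.00217). Ube2d3, Dse and Srp54c were listed at 0 in all 4 Ctrl libraries. Ube2d3 was at 1.45, 1.77 and 1.92 TPM in 3 KO libraries and at 745 TPM in KO library 2, and its call was lost without Ctrl replicate 2 (adjusted p = 0.0592) or Ctrl replicate 4 (0.064), under both scalings, with a pseudocount of 5 (0.0842) and with robust fitting (0.092). Dse, an enzyme of dermatan sulfate synthesis, was at 1.03 to 23.2 TPM in KO. The other genes that the naming rule gave among the 12 largest rises were Ect2, Nsf, Tfap2c, Mapkap1, Cep57l1 and Med23. Their log2 fold changes ran from 2.48 to 2.68. The rule left out predicted genes and genes whose groups overlapped, and some of the latter rose more, by up to 3.81 on the log2 scale.

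Some of these values are uncertain because near-identical sequences elsewhere in the genome could take or give reads. Of 66 named genes or list members searched, 23 shared a stretch of at least 200 bp and 95% identity with another annotated gene. Srp54c shares such stretches with Srp54a and Srp54b, and the mean of the listed row of Srp54a was 60.2 ± 18.9 TPM in Ctrl and 29.4 ± 7.62 TPM in KO (SD, n = 4 each), a call lost under both scalings and without Ctrl replicate 2 (adjusted p = 0.0671), Ctrl replicate 4 (0.061) or KO replicate 2 (0.0634). Hnrnpa3, Hspa8, Dnaja1, Rrm2b, Rps14, Rpl22, Eif4e1b, Cox7a2l, Mrps21, Hbs1l and Ube2d3 were in the same position, and Tcp1, Mrpl13, Ube4b and Usp46 shared sequence with other annotated genes as well.

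**Figure D2:**
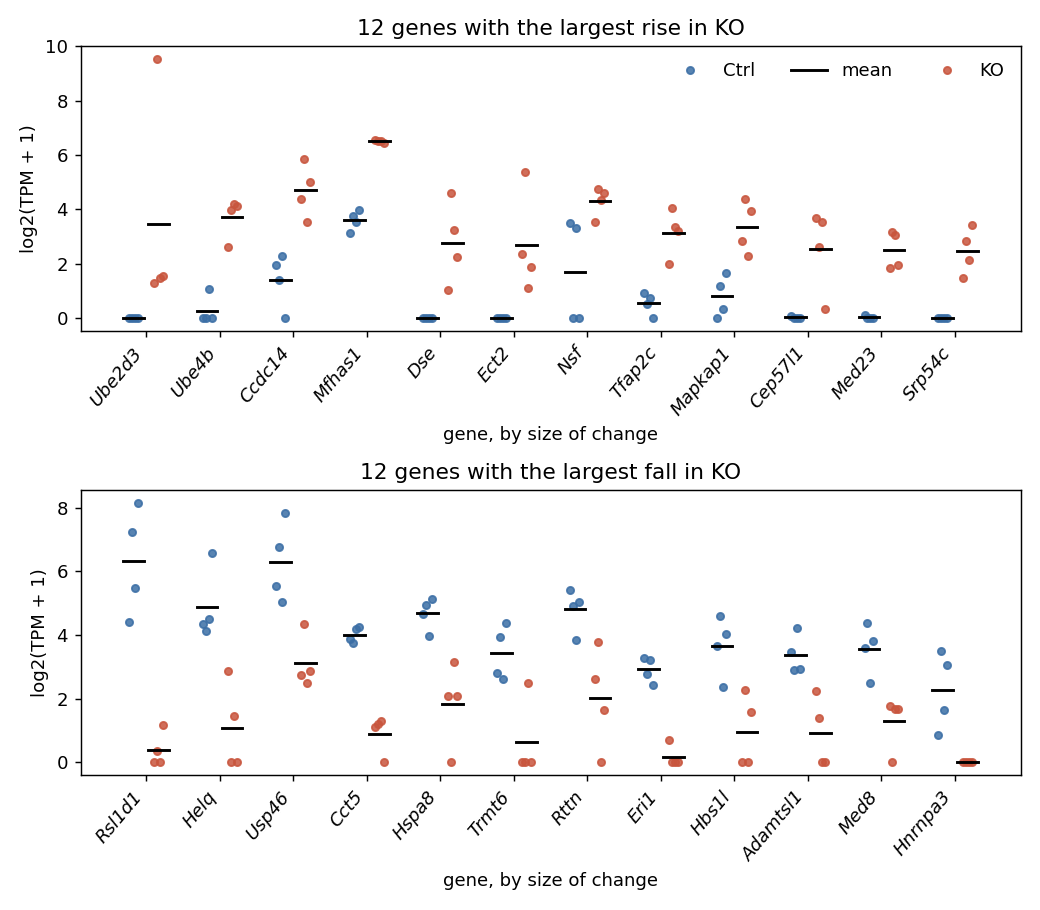
Levels as log2(TPM + 1) in each of the 4 Ctrl (blue) and 4 KO (red) libraries for the 12 named genes with the largest rises (top) and the 12 with the largest falls (bottom), with black bars at the group means. The naming rule took only genes with all KO points on one side of the Ctrl points. The highest Ube2d3 point is KO library 2 at 745 TPM.

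The split between higher and lower genes depended on the scaling of the libraries. The deposited TPM gave 61.0% of the changed genes lower, median-of-ratios scaling gave 145 higher and 52 lower (26.4% lower), and quantile normalization gave 146 higher and 94 lower (39.2% lower). The median log2 fold change over the tested genes was -1.05 with the deposited TPM and moved by 0.70 under median-of-ratios scaling and by 0.37 under quantile normalization. Of the 52 genes that the naming rule gave and that passed, 19 lost their call under at least 1 of these scalings. Both scalings were computed from rows picked for their difference, so they take out part of what those rows share. A call lost under them is therefore not evidence that the gene did not change. Over the listed rows, Ctrl libraries 2 and 4 had median-of-ratios factors of 1.66 and 1.79, against 1.11 and 0.93 in Ctrl libraries 1 and 3. KO library 2 had the lowest factor, 0.53. These factors hold any difference that the picked rows share between the groups. The count of changed genes was 188 without Ctrl replicate 2, 244 without Ctrl replicate 4, 215 without KO replicate 2, and 54 without Ctrl replicates 2 and 4 together, an alternative chosen after seeing the data.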

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

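The summed level of mt-Nd3 with its nuclear copy, the count of other genes with copies and the test of other scalings were chosen after the results were seen. A library far from the other 3 of its group, by Dixon's ratio of the gap to the range on log2(TPM + 1), was found in 20 of 134 groups of 4 libraries. Chance gives about 1 in 20 groups, or 6.7 here. The most, 5, were in KO library 2.

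KO library 2 was highest for Ube2d3 (745 TPM, ratio 0.969) and lowest for Med8 (0 TPM, 0.935), Nlrp9b (67.2 TPM, 0.941), mt-Nd2 (315 TPM, 0.839) and Tcp1 (0 TPM, 0.854). KO library 1 was lowest for Ube4b (5.06 TPM, 0.867). Ctrl library 4 was highest for Helq (94.0 TPM, 0.845) and mt-Nd5 (575 TPM, 0.876), and Ctrl library 2 was lowest for Dcp1a (0.658 TPM, 0.830). KO library 4 was lowest for Cct5 (0 TPM, 0.854).

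In the other groups all or nearly all of the remaining libraries were at or near 0, so a single small value gave the ratio. This held for Ctrl library 3 of Ube4b (1.10 TPM, 1), for Ctrl library 1 of Ect2 (0.0025 TPM, 1), Cep57l1 (0.0545 TPM, 0.928) and Med23 (0.0784 TPM, 1), and for Ctrl library 2 of Brca2 (0.565 TPM, 1). It also held for KO library 3 of Trmt6 (4.61 TPM, 1) and Cep192 (3.15 TPM, 1), for KO library 1 of Eri1 (0.613 TPM, 1) and Hnrnpa3 (0.0076 TPM, 0.837), and for KO library 4 of Psma6 (1, at a value near 0).

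The lower level of the 10 mitochondrially encoded genes could have come from KO library 2, which stood lowest. Without it all 10 still passed, which argues against that library as the whole source. Reads moving from mt-Nd3 to Gm28438 would leave their sum unchanged, but both fell and so did the sum (log2 fold change -2.20, SE 0.68), which argues against such a shift, for this gene only. For 6 others of the 10 genes (mt-Atp6, mt-Co3, mt-Nd2, mt-Nd4, mt-Nd4l and mt-Nd5) no nuclear copy found has a row, so reads moving to copies stay open there. A single factor acting on all mitochondrial transcripts stays open: relative to the mean of the 10 genes in each library, the groups were not told apart (exact permutation p = 0.171), which does not show that the proportions were equal. Only 10 of the 15 mitochondrially encoded genes of the list have a row, and the rows were picked for their difference. The test therefore cannot show whether the remaining genes fell too. A common factor may be the genotype itself or the handling of the libraries, and these data do not separate them.

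More genes were lower than higher in KO. Among the listed genes, the log2 fold change did not follow the mean length of a gene's annotated transcripts. Spearman rho was 0.027 (95% bootstrap interval -0.075 to 0.132, across 401 genes, which are not independent replicates). This covers neither the lengths of the transcripts behind the rows nor how the rows came to be listed, so length stays open there. For GC content rho was 0.125 (0.025 to 0.22), below the size set for an explanation but not near enough to 0 to leave it out. A scale difference between the libraries also stays open, because 26.4% of the changed genes were lower under median-of-ratios scaling. That scaling centres rows that were picked for their difference, so it cannot decide the matter. The genotype is the biological explanation the design names, and it was not tested apart from these.

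The real grouping gave 377 changed genes and was 1 of 35 splits of the 8 libraries with as many; the highest of the other splits gave 3. As the rows were picked by this contrast, that comparison cannot exclude chance.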

How the results depend on the processing

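Rows kept unsummed and Ctrl replicates 2 and 4 left out together were chosen after seeing the data. The count of 377 changed genes (147 higher, 230 lower) stayed within 1.5 times under both pseudocounts, no filter, the variance models, array weights, the 2-fold minimum, rows kept unsummed and the mitochondrially encoded genes left out, with 301 to 426 genes. A mean of at least 5 TPM gave 213 (74 higher, 139 lower) because only 230 genes were tested. Median-of-ratios scaling gave 197 (145 higher, 52 lower) and quantile normalization 240 (146 higher, 94 lower). Both were computed from the listed rows alone, whose median log2 fold change was -1.05 with the deposited TPM. They moved that median up by 0.70 and 0.37, and the calls lost were mostly of lower genes. Neither can tell a scale difference from a change of the picked rows. Leaving out 1 library gave 188 to 358 changed genes, 74 to 140 higher and 114 to 228 lower. The lowest counts were 188 without Ctrl replicate 2, 215 without KO replicate 2 and 244 without Ctrl replicate 4. Without Ctrl replicates 2 and 4 together 54 passed (26 higher, 28 lower), with fewer samples. Of the 52 genes that the naming rule gave and that passed, 31 passed under every planned setting that tested them, 10 lost their call without at least 1 library and 19 under at least 1 scaling. None of them reversed. Under quantile normalization 2 other called genes changed sign, mt-Nd2 to 0.0553 and Gm20594 to 0.16, both named after their values were seen. Quantile normalization sets values by rank, and mt-Atp6 and mt-Cytb shared ranks 1 and 2 in all 8 libraries, so it says nothing about their fall.

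With the replicate block 279 genes passed (112 higher, 167 lower). It ended the calls of Dap3 (limma adjusted p = 0.088), Dnmt1 (0.0635), Cnot6l (0.0502) and Srp54a (0.0736). The replicate numbers share only a label: the deviations of same-numbered libraries correlated at -0.26, -0.20, -0.17 and 0.07, and no Ctrl library correlated best with the KO library of its own number.

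For the mitochondrially encoded list the camera adjusted p of 0.0325 went to 0.065 with a pseudocount of 0.1, 0.0883 under median-of-ratios scaling, 0.808 under quantile normalization, 0.0615 with the replicate block and 0.704 with an estimated correlation, and leaving out 1 library gave 0.0153 to 0.0796. By camera, the chaperone list passed only with a mean of at least 5 TPM (0.0386). That filter leaves out the low risers Cct4 and Hsf1, and the 6 genes kept all fell. Over 20 alternatives at the preset correlation the camera adjusted p ran from 0.0386 to 0.686, and with an estimated correlation it was 0.704. Depth is unknown, so the precision of single low values is unknown too.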

Other observations

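The tests in this part were chosen after the results were seen. Among the 386 tested nuclear protein-coding genes, 16 pairs were direct neighbours with no other protein-coding gene between them, 10 with log2 fold changes of the same sign and 6 of opposite sign. In 1 of the latter, Cttn and Ppfia1, Ppfia1 did not pass (limma adjusted p = 0.0589). The gene models of Cpne1 and Gm28036, a pair of the same sign, overlap, so reads could be shared between them. Pum2, lower in KO with a call lost when single libraries were left out, lies next to Sdc1, a heparan sulfate proteoglycan. Sdc1 was higher (log2 fold change 1.73, limma adjusted p = 0.0144). The groups overlapped for both Pum2 and Sdc1. Cttn, Ppfia1, Cpne1, Gm28036 and Sdc1 were named after their values were seen.

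The pair of Eri1, lower in KO, and Mfhas1, higher, stood out because both were among the genes with the smallest p, at ranks 5 and 2. Overlapping gene models sharing reads are argued against by the 91601 bp between them. A pair of direct neighbours turned up in 0.963% of 100000 random draws of 10 listed genes. Since the pair was noticed before it was tested, chance may still account for it. A variant or insertion at the locus carried by one genotype could change both genes at once. Of the 11 annotated protein-coding genes within 1 Mb of the pair or in it, 0 others were listed, and as genes without a row were not analysed here, this hypothesis stays open beside an effect of the genotype.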
